A study of Drosophila melanogaster with 3 samples.

How the data were processed

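The series measured where the protein encoded by croc (crocodile, a forkhead-domain transcription factor) sat on the genome of Drosophila melanogaster embryos. Per the labels, transgenic flies carried croc fused to enhanced green fluorescent protein (croc-eGFP), chromatin of whole embryos aged 0 to 18 h was sonicated to 200 to 800 bp, and fragments were immunoprecipitated with an antibody against GFP and sequenced (ChIP-seq). The 3 samples are biological replicates 1, 2 and 3 of 1 group, per the labels. Control libraries were not analysed here.

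The deposited files are peak lists on the dm6 build, per the file listings deposited with the samples. Each replicate has a ranked list and a thresholded list, both made by IDR, the irreproducible discovery rate, which scores a peak by how well its rank repeats between a pair of lists. The whole series has 4 ranked lists, 3 thresholded lists and 1 conservative thresholded list. The aligner, the peak caller and their versions are not given in the sources used here. The deposited signal value is the peak caller's own value for each peak, its scale is not stated, and it was used only to rank or filter peaks within a list. The deposited score is the scaled IDR score, capped by its layout, and the lowest score in the thresholded lists was 830. The −log10 of the global IDR in the deposited ranked lists was used to check which peaks passed the threshold. The conservative list was contained in a ranked list of 17254 peaks, of which 3668 had a score of at least 830 and 3650 were kept. What removed the other 18 is not given in the sources used here. In that ranked list, 85.1% of the first set of replicate intervals were intervals of the ranked list of replicate 1 and 87.5% of the second set were intervals of the ranked list of replicate 2. The share found in the ranked list of replicate 3 was 0%. No read counts were used here, so the depth of each library is unknown. Intervals given for shares of peaks are exact (Clopper-Pearson) 95% binomial intervals, and they treat peaks as units. Peaks are not independent samples, so p-values across peaks describe these lists and not the spread between embryos.

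Coordinates were compared with a Release 6 reference sequence, and every peak on arms 2L, 2R, 3L, 3R, 4 and X lay inside the arm of that name. Comparisons used these 6 arms. Peaks on unplaced scaffolds were left out of the comparisons and counted separately. The BDGP6.54 gene annotation gave 13945 protein-coding genes on the arms, of which 13741 had positions nearest to their own transcription start site (TSS) and could receive a peak. A peak was assigned to the gene with the nearest protein-coding TSS, within 10 kb. A summit within 500 bp of a TSS was called promoter. Summits within 250 bp of each other in different lists were counted as shared.

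These tests were fixed before the data were examined. Replicate overlap was the percent of each thresholded list with a shared summit in both other replicates, set against 100 random rotations of the lists along the arms. The promoter share was compared with 10 uniform positions per peak on the same arm by a 2-sided Fisher's exact test, and the share on X with the share of X in arm length by a 2-sided exact binomial test. The forkhead consensus TRTTTAY (R is A or G, Y is C or T) was searched on both strands within 50 bp of each summit and within 50 bp of the position 500 bp to its left, with an exact McNemar test. Every distinct reordering of its letters was searched in the same way. For 16 gene lists, the number of members with an assigned conservative peak was compared with 10000 random lists matched on the decile of the length of sequence nearest to each gene, with a one-sided permutation p adjusted by Benjamini-Hochberg over the lists. A list passed the test at an adjusted p under 0.05. Lower-tail p-values for the lists were added after seeing the data. Symbols of the lists were matched to the annotation, and unmatched symbols were not analysed here.

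The rule for named genes was croc itself, the genes assigned to the 20 strongest conservative peaks shared with all 3 replicates, and the 3 members of each list with the strongest peak. Genes named outside this rule are marked as chosen after their values were seen. Alternatives were other distances, overlap rules, peak subsets, motif windows, backgrounds and gene assignments, and leaving out each replicate, which for the conservative list meant keeping only its peaks shared with both other replicates. Windows of the same AT content (10 per peak, over 1000 bp from every ranked peak of a replicate), the mean of the reordered words as a background, replicate lists for the gene lists, and the removal of peaks with a stronger summit within 1 peak width (384 bp) were added after seeing the data.

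The statistics were tested on simulated data. Of 2000 simulated peaks per list with 50% planted as shared, 50.2% were recovered as shared. In 3600 AT-rich genome windows with nothing planted, the forkhead ratio to windows of the same AT content was 0.978, and after planting the motif in 10% of the windows it was 1.30. Over 13741 genes, 88.5% of 200 simulated lists with planted members and 0.5% of 600 without were called. Each member of a planted list had a 50% chance of an added peak, and all simulated lists had the same size. The 88.5% is therefore not the power of the test for smaller lists or weaker effects. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.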

Results

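Binding of croc-eGFP was profiled in 3 biological replicates of whole embryos aged 0 to 18 h. The thresholded lists held 3198 peaks in replicate 1, 2433 in replicate 2 and 1822 in replicate 3 (mean 2484 ± 689 SD, n = 3). The conservative list of the whole series held 3650 peaks, 3644 of them on the 6 chromosome arms. Signal values below are the authors' values within that list. The series has 1 group, so the comparisons are between replicates, and between peaks and the rest of the genome.

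The first comparison asked how far the replicates placed peaks at the same positions. Of the peaks of replicate 3, 83.0% lay within 250 bp of a summit in both other replicates, against 62.8% for replicate 2 and 47.3% for replicate 1 (mean 64.4% ± 17.9 SD, n = 3). About as many peaks were shared from each side: 1510 of 3195 in replicate 1, 1512 of 2408 in replicate 2 and 1507 of 1815 in replicate 3. Rotating the lists along the arms gave at most 0.110% in 100 draws. Among the strongest 50% of each list by signal, 89.7% of peaks on average were shared with the full lists of both other replicates. Across shared peaks, signal ranks had a Spearman correlation of 0.865 between replicates 1 and 2 (2125 peaks), 0.808 between replicates 1 and 3 (1663 peaks) and 0.800 between replicates 2 and 3 (1563 peaks). These correlations are across peaks, which are not independent samples. In the conservative list, 1589 peaks (43.6%) had a shared summit in all 3 replicate lists, 879 in 2, 796 in 1 and 380 in none. Neighbouring conservative peaks can be shared through the same replicate summit, so these are counts of peaks and not of separate sites. The conservative list was drawn from replicate peaks mostly of replicates 1 and 2, so sharing with those replicates is partly built in. A peak shared with none lacked a summit within 250 bp in the thresholded replicate lists, and the ranked lists were not counted. The median signal was 328.6 for peaks with 3 supporting replicates and 110.9 for those with none.

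The croc gene itself (FBgn0014143, 3L 21474133 to 21476479, minus strand, dm6) was nearest to 5 conservative peaks, all intergenic. The strongest had its summit at 21464504 on 3L, a signal of 361.1 and rank 688 of the list, 11975 bp from the TSS, and was shared with all 3 replicates. Another, with its summit at 21479824 on 3L, 3345 bp from the TSS, had a signal of 113.0 and was shared with replicates 1 and 2. It was the peak assigned to croc under the 10 kb limit. The other 3 summits lay 10280, 13040 and 13321 bp from the TSS, with signals of 151.1, 27.0 and 112.1. The peak with a signal of 27.0 was shared with no replicate's thresholded list and lay within 1 peak width (384 bp) of the stronger summit at 21463158; of the 388 peaks of the list with a signal under 50, 376 had such a neighbour.

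**Figure D1:**
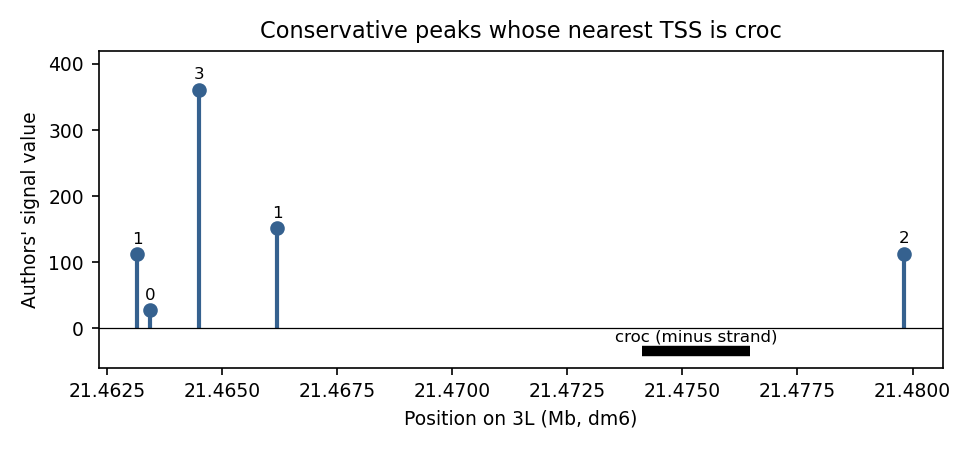
Conservative peaks whose nearest TSS is that of croc. The horizontal axis is the position on 3L in Mb (dm6), the vertical axis the authors' signal value, and the number above each point the count of replicate lists that shared the summit; the black bar is the croc gene. The strongest peak, at 21464504, has a signal of 361.1, and 4 of the 5 peaks lie beyond the 3' end of the gene.

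The 20 strongest conservative peaks were all shared with the 3 replicates and had signals from 1722 to 3101. Of these summits, 13 lay at promoters, 5 in introns and 2 between genes, and 19 were assigned to a gene. The strongest peak (X 2703702 to 2704068) lay 31 bp from a TSS of Ugalt, a UDP-galactose transporter gene, with a signal of 3101. The next was 89 bp from CG14100 (3L 19590439 to 19590794, signal 3031). The third lay 1404 bp from the TSS of cbt, a zinc-finger transcription factor gene, outside cbt itself and in an intron of ush, which spans it (2L 480904 to 481280, signal 2914). The Polycomb group gene ph-p followed with a signal of 2767 and a summit 486 bp from its TSS (X 2137175 to 2137540), then the wing vein gene px with 2670 (2R 22514125 to 22514492). Genes of mitochondrial ribosomal proteins, mRpS10 and mRpL41, had promoter peaks with signals of 2330 and 2232. Promoter peaks of this set also lay at Chro, which encodes the chromodomain protein Chromator (2044), CG7601 (1983), CG5611 (1942), Tcs5 (1916), PNPase (1816), CG18549 (1761) and CenG1A (1741). Intronic peaks lay in CG11050 (2407), the transcription factor gene Adf1 (2160), CG32772 (1791) and HmgZ, which encodes a high mobility group protein (1722). An intergenic peak 3768 bp from the TSS of CG31668 had a signal of 1775. The unassigned peak (2R 13035167 to 13035487, signal 2124) was 11953 bp from the nearest TSS, that of CG13323.

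Promoters held a larger share of peaks than their share of the genome. Of the conservative summits, 40.6% (95% interval 39.0 to 42.2, 1478 of 3644) lay within 500 bp of a protein-coding TSS, against 11.4% of uniform positions (odds ratio 5.32, 2-sided Fisher's exact test with a p too small to be represented). The replicate lists gave 42.9% ± 4.04 (SD, n = 3). Introns held 37.3% of summits against 39.6% of uniform positions (odds ratio 0.907, adjusted Fisher's exact p = 0.00912) and intergenic sequence 20.7% against 29.6% (odds ratio 0.620, adjusted p = 3.36e-31). Coding exons outside promoters held 11 summits, 0.302% against 14.2% (odds ratio 0.0184, adjusted Fisher's exact p = 5.42e-207), and 3' UTRs 0.741% against 4.64%. The median distance to a TSS was 1003 bp for summits and 4197 bp for uniform positions. Within 500 bp of tRNA genes lay 5 summits, 0.137% against 0.148% (Fisher's exact p = 1). The promoter share was 50.8% in the strongest 20% of peaks by signal and between 35.4% and 41.8% in the 4 weaker bins of that size.

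**Figure D2:**
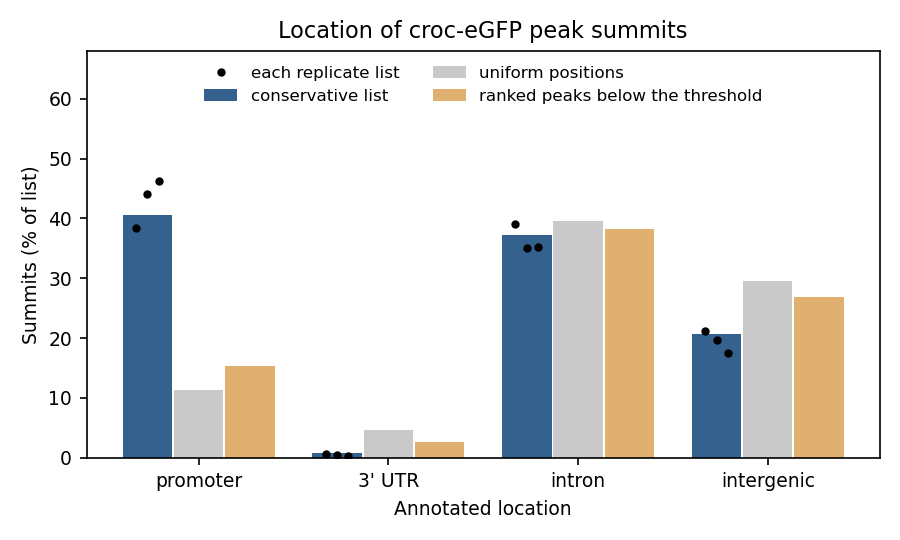
Share of summits by annotated location for the conservative list (blue), uniform positions (grey) and ranked peaks that did not pass the threshold (orange), in percent of each list; black points are the 3 replicate lists. Classes with 20 or fewer conservative peaks are not drawn. Promoters hold 40.6% of conservative summits, 11.4% of uniform positions and 15.4% of ranked peaks below the threshold.

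Peaks were spread unevenly over the chromosome arms. The X chromosome held 699 of 3644 summits, 19.2% (95% interval 17.9 to 20.5), against 17.6% of arm length (ratio 1.09, 2-sided exact binomial p = 0.0123, adjusted over 6 arms 0.0246). The replicate lists gave 19.1% ± 0.853 (SD, n = 3). Chromosome 4, which is largely heterochromatic, held 9 peaks, 0.247% against 1.01% of length (ratio 0.245, adjusted exact p = 4.74e-07). Arm 2L held more than its share (ratio 1.08, adjusted exact p = 0.0292), 2R less (ratio 0.902, adjusted p = 0.0128) and 3R less (ratio 0.933, adjusted p = 0.0292), and 3L did not pass the test (ratio 1.05, adjusted p = 0.0995). Of ranked peaks below the threshold, 13.2% lay on X (ratio 1.46, Fisher's exact p = 4.71e-22) and 19.1% on 2L, where the conservative list had 19.0%. That background held less of X than the 17.6% of arm length, so the ratio of 1.46 overstates the excess over length. The cause of its low share on X was not tested. The X call against arm length did not hold among peaks shared with all 3 replicates (ratio 1.10, exact p = 0.0700) or those shared with replicates 2 and 3 (ratio 1.08, exact p = 0.135).

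Forkhead proteins bind sequences of the type TRTTTAY. This consensus lay within 50 bp of 23.6% of conservative summits and in 14.1% of windows of the same size 500 bp to the left (ratio 1.67, exact McNemar p = 7.20e-25). The replicate lists gave a ratio of 1.89 ± 0.114 (SD, n = 3). By signal, the consensus was in 27.3%, 26.3%, 23.9% and 24.3% of summits in the 4 stronger bins of 20% of peaks each, and in 16.3% in the weakest bin, which holds the 388 peaks with a signal under 50. Summits were also richer in A and T than their flanks: 67.6% against 56.3% of bases in the conservative list, and 69.3% ± 0.533 against 56.3% ± 0.108 in the replicate lists (SD, n = 3). Of the 209 other orderings of the letters of the consensus, 84 were found at more summits than the consensus itself and 197 had a higher ratio of summit to flank (median 2.01). Against genome windows of the same AT content, of which 23.3% held TRTTTAY, the ratio was 1.01 (95% interval 0.953 to 1.08, Fisher's exact p = 0.681), a comparison added after seeing the data. Those windows were not matched on distance to a TSS. The strict core TGTTTAC was in 2.44% of summits and 1.81% of flanks (exact McNemar p = 0.0769).

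**Figure D3:**
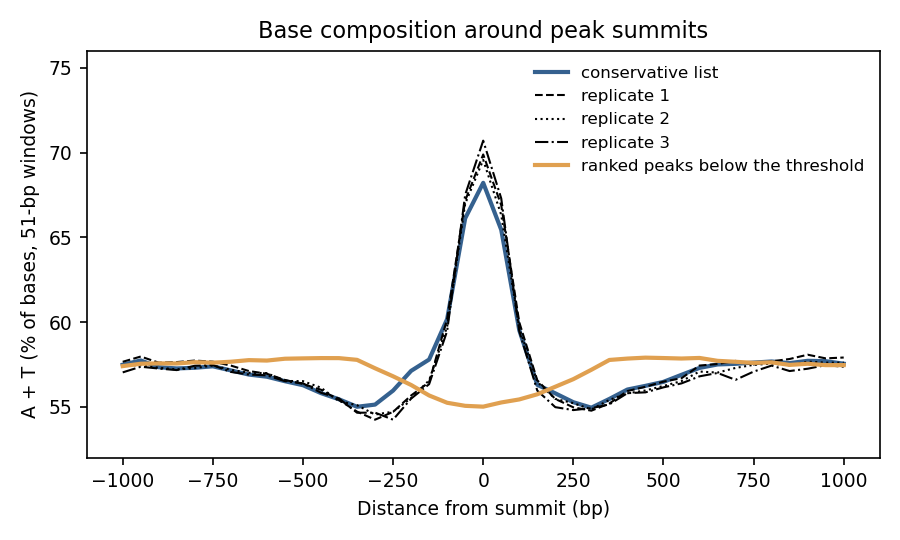
Percent of A and T in 51 bp windows (vertical axis) by distance from the summit in bp (horizontal axis, from −1000 to 1000) for the conservative list, each replicate's thresholded list and ranked peaks below the threshold. At the summit the conservative list reaches 68.2% and the replicate lists lie between 69.6% and 70.7%, while the peaks below the threshold have 55.0%.

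The fixed gene lists asked which groups of genes carried assigned peaks. In all, 3225 conservative peaks were assigned to 2166 genes, 15.8% of the 13741 genes that could receive one. Of the 16 lists, 2 had more members with a peak than matched random lists, the epidermal growth factor (EGF) receptor pathway and the ribosomal proteins. In the EGF receptor pathway, 9 of 11 members had a peak, against 3.27 for random lists (one-sided permutation p = 7.00e-04, adjusted p = 0.00560), and each of the replicate lists had 8. When genes were matched on their number of ranked peaks in place of sequence length, the ratio to random lists fell from 2.75 to 1.53 and the call was lost (adjusted permutation p = 0.370, the highest over 14 alternatives, the lowest being 8.00e-04). Ranked peaks include the tested peaks, so this matching can also take away true enrichment. The strongest peaks of this pathway were at aos, which encodes a secreted antagonist of the pathway (signal 910.4), edl (813.8) and S, which encodes the ligand-processing factor Star (593.9). These peaks were all intronic and shared with all 3 replicates. Of the ribosomal protein genes, a housekeeping comparison list, 39 of 92 had a peak against 11.3 for random lists (p = 1e-04, the smallest that these permutations can give, adjusted p = 0.00160). The lists of replicates 1, 2 and 3 had 34, 36 and 19, and peaks shared with all 3 replicates had 15 (ratio to random lists 2.51, adjusted permutation p = 0.00880; from 8.00e-04 to 0.00880 over 14 alternatives). The strongest were promoter peaks at RpL7 (496.8), RpS27 (472.0) and RpL32 (448.9). Of the adult chemosensory receptor genes, 3 of 117 had a peak against 18.1 for random lists (lower-tail permutation p = 1e-04, adjusted p = 0.00160). These were Gr93a (570.4), Gr89a (202.7) and Gr93d (170.7). The ribosomal and chemosensory lists were both chosen for comparison, and both departed from random lists matched on sequence length. A call under this matching therefore does not by itself mark a list as particular to croc-eGFP. Whether genes active in embryos gained peaks in general was not tested.

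**Figure D4:**
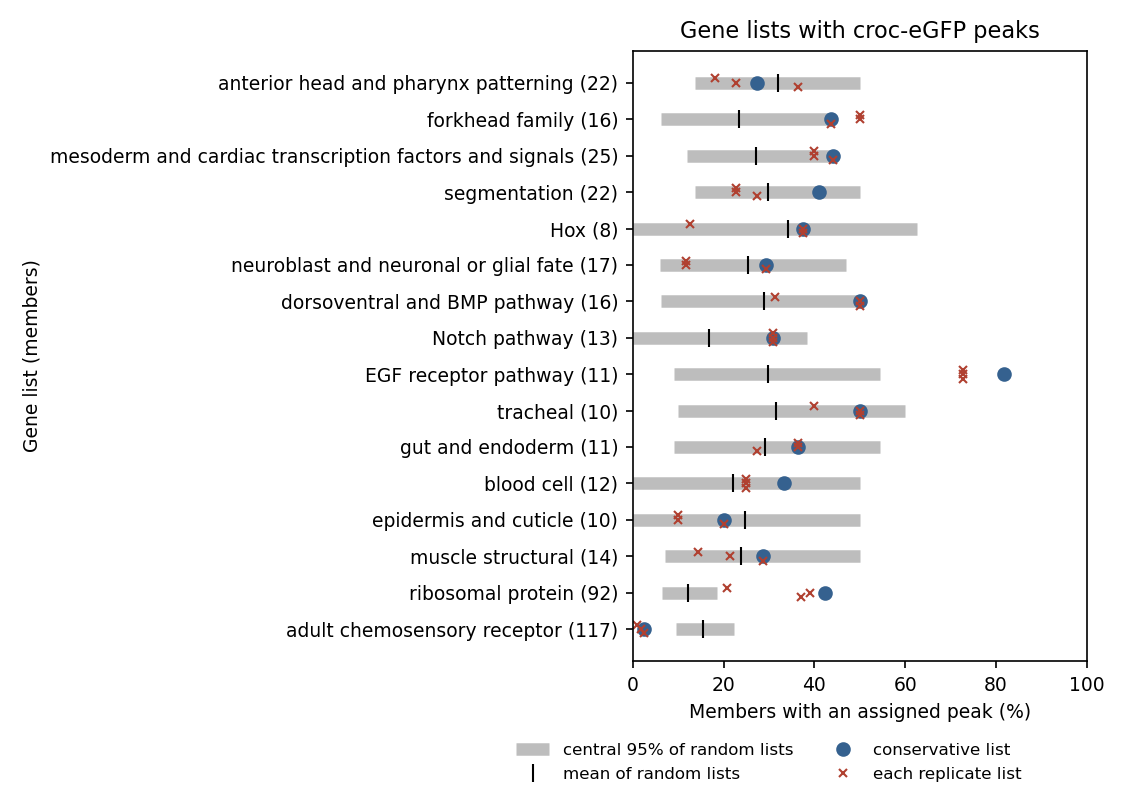
Percent of the members of each fixed gene list with an assigned peak (horizontal axis), with the number of members in brackets. Blue points are the conservative list, crosses the 3 replicate lists, ticks the mean and grey bars the central 95% of matched random lists. The EGF receptor pathway (81.8% against 29.7%) and the ribosomal proteins (42.4% against 12.3%) lie above the bars and the chemosensory receptors (2.56% against 15.5%) below. Random lists here are matched on sequence length. The EGF receptor call was lost when they were matched on ranked peaks, whose counts include the tested peaks.

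Among the developmental regulators, several lists had more members with a peak than the mean of random lists without passing the test. In the forkhead family, 7 of 16 members had a peak against 3.74 (adjusted permutation p = 0.166), with the strongest at the segmentation gene slp2 (971.6), CHES-1-like (787.6) and the insulin-signalling effector foxo (698.3); each of the 7 had its strongest peak shared with all 3 replicates. In the mesoderm and cardiac list, 11 of 25 had one against 6.78 (adjusted permutation p = 0.166), led by zfh1 (676.2), the myoblast fusion gene kirre (656.2) and the heart determinant tin (532.1). In the dorsoventral and BMP list, 8 of 16 had one against 4.62 (adjusted permutation p = 0.166), led by brk (430.5), dpp (363.1) and ush (356.0). Among peaks shared with all 3 replicates, 4 lists passed, including the forkhead family (adjusted permutation p = 0.0112) and the mesoderm and cardiac list (adjusted p = 0.0164). Matched on ranked peaks, whose counts include the tested peaks, the forkhead and the mesoderm and cardiac lists had ratios of 1.49 and 1.07 to random lists (adjusted permutation p = 0.663 and 0.882). By gene body the ratios were 1.24 and 1.17 (adjusted permutation p = 0.980 for both). Over 14 alternatives their adjusted p ranged from 0.00213 to 0.980 and from 0.00373 to 0.980. The dorsoventral and BMP list passed among peaks shared with replicates 1 and 2 (adjusted permutation p = 0.0388), in the list of replicate 2 (adjusted p = 0.0488) and without matching (adjusted p = 0.00600), and its adjusted p reached 0.882 when matched on ranked peaks. In the Notch list, 4 of 13 had one against 2.18, led by E(spl)m3-HLH (483.3), E(spl)m7-HLH (467.8) and neur (325.9). In the segmentation list, 9 of 22 had one against 6.54, led by nkd (377.2), ptc (358.9) and slp1 (317.7). That count was 6, 5 and 5 in the lists of replicates 1, 2 and 3, and 3 among peaks shared with all 3 replicates, below random lists (ratio 0.890). The adjusted permutation p was 0.358 for the Notch, segmentation and tracheal lists; without matching the segmentation and tracheal lists passed (adjusted permutation p = 0.0118 and 0.0290). In the tracheal list, 5 of 10 had one against 3.15, led by rib (447.6), trh (265.0) and tai (229.6).

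The other lists did not pass the test either, with adjusted permutation p-values between 0.453 and 0.813. In the anterior head and pharynx list, 6 of 22 members had a peak against 7.04 for random lists, with the strongest at slp2, slp1 (317.7) and oc (266.0), and 16 had none. The neural list had 5 of 17 against 4.30, led by elav (918.9), SoxN (210.3) and pros (173.4), but 2 among peaks shared with all 3 replicates, below random lists (ratio 0.907). The gut list had 4 of 11 against 3.20, led by bowl (696.4), aop (583.7) and srp (191.0). The blood cell list had 4 of 12 against 2.64, led by ush, crq (327.0) and srp. The Hox list had 3 of 8 against 2.73, Antp (237.3), abd-A (180.4) and Abd-B (173.4), but 1 among peaks shared with all 3 replicates (ratio 0.709). The muscle list had 4 of 14 against 3.32, led by sls (396.9), Act87E (180.3) and Tm1 (173.7). The epidermis list had 2 of 10 against 2.47, grh (581.5) and ovo (119.9). The direction of each of these lists depended on the setting: over 14 alternatives the ratio to random lists ran from 0.215 to 1.73 for the anterior head and pharynx, 0.593 to 1.86 for the neural, 0.862 to 2.29 for the gut, 0.684 to 2.17 for the blood cell, 0.511 to 2.41 for the Hox, 0.494 to 1.80 for the muscle and 0.281 to 1.28 for the epidermis list. The muscle list had 1 member in the strongest 50% of peaks (ratio 0.494) and a ratio of 0.664 by gene body. Among peaks shared with replicates 1 and 2, the gut list had a ratio of 0.862 and the neural list 0.647. Matched on ranked peaks, 1 list passed, and without matching 7 did.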

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

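The scaffold counts, the tests of low-signal peaks and the test of forkhead sites were chosen only after the values were seen.

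Peaks on unplaced scaffolds were outside every comparison above, and their counts exceeded what a count of 0 allows (3) in 6 thresholded lists. There were 25 in replicate 2, 7 in replicate 3, 6 in the conservative list, and 14, 4 and 8 in the other 3 thresholded lists of the series. All lay on scaffolds named as parts of X, and the strongest in the conservative list had a signal of 647.5. Replicate 1 had 3.

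Summits were AT-rich in every replicate, with an excess over the flanks of 11.3 percentage points in the conservative list. Among peaks outside promoters the excess was 9.63 points (SE 0.246), more than promoter composition alone would give under the bound of 5 points set for it. Ranked peaks below the threshold had an excess of −0.249 times that of the conservative peaks (SE 0.00711), which argues against a general bias of the libraries or of peak calling towards AT-rich DNA as the whole cause. Forkhead consensus sites were at 1.01 times their share in windows of the same AT content, so they did not account for the AT excess in that comparison. Those windows were not matched on distance to a TSS. A bias towards AT-rich DNA, or a preference of the fusion protein, the tag or other chromatin features for it, may remain. With 1 group and no control libraries analysed here, no biological explanation other than forkhead sites was tested.

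The conservative list held 388 peaks with a signal under 50, of which 72.2% had the highest score, against 86.1% of peaks with a signal of 50 or more. For 61.6% of the 388 (95% interval 56.6 to 66.5) the summit lay outside both replicate peaks listed for it, against 0.215% of peaks with a signal of 50 or more. Over the whole list, the summit lay outside both for 52.3% of peaks with a stronger conservative summit within 384 bp and 0.375% of those without. Among low-signal peaks it lay outside both for 228 of the 376 with such a neighbour and 11 of the 12 without. Of peaks with a signal of 50 or more it did so for 6 of the 71 with such a neighbour, and for 7 of all 3256. The pair of replicate peaks listed for a low-signal peak was also listed for a stronger conservative peak in 385 of 388 cases (99.2%, 95% interval 97.8 to 99.8), 11 of the 12 included, against 1.35% of peaks with a signal of 50 or more. This is consistent with low-signal peaks taking the replicate peaks of a stronger one. The score was that of the strongest peak with the same pair in 337 of the 385, but scores are capped, so equal scores do not show a common origin. No biological explanation was tested.

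Replicate 3 had the fewest thresholded peaks. Of 615 peaks of replicate 1 that replicate 2 shared and the thresholded list of replicate 3 lacked, 94.6% had a summit within 250 bp in the ranked list of replicate 3, against 8.28% on average after rotation. These positions may therefore have fallen below its threshold rather than lacked signal. Depth and enrichment of the libraries are unknown, and no biological explanation was tested.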

How the results depend on the processing

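The comparisons with windows of the same AT content, with the mean of the reordered words as background, with replicate lists for the gene lists and without peaks beside a stronger summit were added after seeing the data. The promoter enrichment kept its direction and side of the threshold under each alternative run, with odds ratios from 3.76 (ranked peaks below the threshold as background) to 7.13. Replicate overlap moved by more than its SD of 17.9 only for the strongest 50% of each list (89.7%), matched to the full lists of the other replicates. That SD is the spread between replicates with lists of different length. The mean fell from 64.4% to 47.8% when peaks had to overlap by at least 50% of both. It was 61.9% to 64.6% under the other distance and overlap rules. With a replicate left out, a peak needed a partner only in the remaining other list, an easier condition, and the mean was 71.8% to 77.4%. The mean rank correlation was 0.747 on ranked lists, and the remaining pair gave 0.800 to 0.865 when a replicate was left out. For the results on conservative peaks, leaving out a replicate meant keeping peaks of the same list that both other replicates shared, a stricter subset and not a list remade without that replicate. The replicate peaks listed for the conservative list were mostly those of replicates 1 and 2, so every such subset still rests on that pair. The thresholded lists drawn from replicates 2 and 3 (2903 peaks) and from replicates 1 and 3 (3252 peaks) were not compared in this way. The X ratio was 1.46 against ranked peaks below the threshold, a background with 13.2% of its peaks on X against 17.6% of arm length. Against arm length it was 1.10 among peaks shared with all 3 replicates and 1.08 to 1.12 among peaks shared with a given pair of replicates. The call was lost among peaks shared with all 3 replicates and for the pair of replicates 2 and 3. Fewer peaks were tested in both, with ratios near the main 1.09. The forkhead ratio passed the test with each other flank, window and peak subset, and did not with TGTTTAC only (1.35), windows of the same AT content (1.01) or the mean of the reordered words (1.02). The number of gene lists above chance was 2, and it was 4 for peaks shared with all 3 replicates, 4 for the strongest 50%, 4 to 5 for peaks shared with a given pair of replicates, 7 without matching, 1 when matched on ranked peaks, and 4 each with the lists of replicates 2 and 3. The forkhead family passed under 8 of 14 alternatives (adjusted permutation p from 0.00213 to 0.980), the mesoderm and cardiac list under 7, the dorsoventral and BMP list under 3, the EGF receptor pathway under 13, the ribosomal proteins under 14, and the segmentation and tracheal lists under 1 each. The cause of these changes was not tested, except that matching on ranked peaks uses counts that include the tested peaks. Over 63 named genes and 8 peak subsets or distance limits (504 combinations), the gene had no assigned peak in 53, another strongest peak in 12 and the same one in 439, where its signal is equal by construction. The croc gene had no assigned peak in 5 of the 8. Library depth is unknown, so its effect on the number of peaks was not examined.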

Other observations

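The genes and words below were chosen after their values were seen, apart from the test of divergent promoters, whose prediction was written first.

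Some genes carried many assigned peaks. The counts include peaks with a stronger summit within 384 bp, of which the conservative list held 447. The pair of replicate peaks listed for 418 of these was also listed for a stronger conservative peak. Counts per gene, and counts shared with replicates, may therefore hold the same site more than once. The BMP-pathway transcription factor gene shn had 9 conservative peaks, 7 of them shared with all 3 replicates, and ush had 9, of which 3 were. Tlk had 8 peaks over 61657 bp of nearest sequence, 4 of them shared with all 3 replicates, and mtgo had 8, of which 1 was. Of the genes with 7 peaks, tara had 5 shared with all 3 replicates, apt and tou 3 each, shep 2 and CG43658 1. All 7 peaks at Raf, the kinase that acts below receptor tyrosine kinases, and all 7 at the forkhead gene CHES-1-like were shared with all 3 replicates. Raf was not among the fixed lists and had a strongest signal of 909.7.

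Other short words were compared with windows of the same AT content. These windows were not matched on distance to a TSS, whereas 40.6% of summits lay within 500 bp of one. Words common at promoters could therefore exceed this background whatever protein was precipitated, and promoter peaks were not compared separately. The DNA replication-related element TATCGATA was in 0.933% of summits against 0.324% of matched windows (ratio 2.88, adjusted Fisher's exact p = 6.14e-06) and the GAGA element GAGAG in 9.17% against 7.47% (ratio 1.23, adjusted p = 0.00141), although flanks held more of the latter (14.8%). Of 2080 6-base words, 161 were more frequent at summits than in matched windows and 112 less, at a threshold of 0.05 on the adjusted Fisher's exact p. The word with the smallest p, CAGTGC, was in 5.93% of summits against 2.56% (ratio 2.32, adjusted Fisher's exact p = 7.00e-22), followed by ACAGTG (ratio 2.16) and CAGTGG (ratio 2.02). Among peaks with no stronger summit within 384 bp, the shared core CAGTG was in 13.5% of the strongest 20% (ratio 1.73 to matched windows, 95% interval 1.40 to 2.14) and 23.1% of the weakest 20% (ratio 2.24, 95% interval 1.91 to 2.62). No factor that reads this word was tested.

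One hypothesis was that promoter peaks favour divergent promoters, where a neighbouring gene starts on the other strand within 500 bp upstream. Of 1303 genes with a promoter peak, 38.9% had such a neighbour, against 21.9% of genes without one in the same decile of sequence length. The ratio was 1.77 (95% interval 1.65 to 1.89 over 2000 resamples of genes). The ratio lay in the direction of the hypothesis, but open chromatin at such promoters was not measured here. A peak at a divergent promoter was assigned to 1 gene of the pair, so the other could count as lacking one. That would raise the share of 21.9% and lower the ratio.

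In the ranked list that holds the conservative list, most of the listed replicate peaks were intervals of replicates 1 and 2, and none was an interval of replicate 3 (85.1%, 87.5% and 0%). The corresponding shares were 88.2% and 89.3% for replicates 2 and 3 in a list of 14749 peaks, and 83.0% and 87.3% for replicates 1 and 3 in a list of 20021 peaks. The remaining ranked list of the series, with 9999 peaks, did not follow this pattern: 9.14% of one set of its listed peaks were intervals of replicate 2, and the other shares were at most 0.0388%. All 3 alignments are listed among the sources of these lists, per the deposited file listings. The 4 ranked lists also had the same highest signal (3101) and the same lowest signal (2.01), whichever replicates their listed peaks came from.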
